A study of Mus musculus with 12 samples.

How the data were processed

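Total RNA was extracted with TRIZOL and purified on columns, per the labels' protocols. Per the same source, the NuGEN Ovation RNA-Seq kit was used for the myoblast libraries and the NuGEN complete RNA-Seq protocol for the muscle libraries, so that kit and tissue cannot be separated. The mice were C57Bl/6. Knockout and wild-type animals of a litter came from matings of heterozygous parents, 2 knockouts were processed in parallel, and a single wild type was taken per litter, per the series' design text.

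The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, calculated by the authors, with a single value per gene and group and no counts. The genome build mm9 is named in the submitters' processing notes. The aligner, the quantification tool, the annotation and the way in which 2 samples became a single column are not given in the sources used here. The 7 value columns were matched to groups by name, with 0 columns of values left unmatched, and the wild-type myoblast columns each matched a single sample title. No coordinates are given, because the reference at hand, GENCODE M21, is of another build. It served only for the lengths of 4179 genes with a single transcript, from which the FPKM value of a single fragment was estimated as the most frequent product of FPKM and length. Whole counts could not be recovered.

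The choices made before the data were examined included a linear model with moderated variances, gene set tests, omission of each library in turn, replicate blocks and several forms of variance prior. None of these could be run as planned, since a column per group leaves no spread within groups, and the analysis was descriptive. The exception was a limma fit (version 3.58.1, R 4.3.3, variance prior with trend) of the 4 myoblast columns with both wild types as 1 group, added last. Its spread comes from 2 libraries of different litters (1 residual degree of freedom, 25.8 from the prior), and the knockout columns are assumed to vary like them. Differences were calculated on log2(FPKM + 1), a pseudocount of 1, over genes with a mean of at least 1 FPKM in the columns of the tissue, or of all columns for comparisons of tissues. A gene listed at 0 in a compared column was left out of that comparison, as an exact 0 can be a failed estimate. A change of 2-fold on this scale, a log2 value of 1, took the place of a test threshold, a rule set after the table was seen. It says nothing of reproducibility between animals.

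Myoblast knockouts were compared with the wild type of their own litter, and both muscle knockouts with the shared wild-type column. Gene groups came from 39 lists fixed beforehand, with 8 members not matched to the table, and 3 lists (lymphoid, pancreas, brown fat) added after the values were seen. Lists overlap: the sarcomere list shares 11 members with the fast-fibre list, 8 with the slow-fibre list and 6 with the developmental list. For each list of at least 5 compared genes, the median change was set beside the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression. Their central 95% describes these libraries and is not a test of the conditions. The named genes were, by rule, the 8 largest rises and falls at 2-fold or more, leaving out small RNAs and predicted genes, with Lbr, Lmna, Lmnb1, Lmnb2 and Emd in each knockout comparison and up to 4 members of each described list by size of change. For differences of effects and for tissue, the 5 largest in each direction were named. A few genes that meet these rules are not printed. The planned order by p and the condition on replicate overlap could not be applied. The Y-linked genes Ddx3y and Eif2s3y, the genes listed at 0, some genes shared between comparisons (Actn2, Coro1a, Gm1987 and Gm7325) and Myog in the Lmna knockout lie outside this rule and were chosen after their values were seen.

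The calculation was tested on simulated data for each of the 4 knockout comparisons, with 200 genes changed and a noise SD of 0.1 on the log2 scale. Of the genes changed 3-fold, 100% were recovered in both myoblast comparisons (11315 and 11393 genes) and in Lbr muscle (11823 genes), and 98% in Lmna muscle (11827 genes). Genes changed 1.5-fold were recovered in 0% of cases and there were 0 false calls. The fixed rule and the low noise set this outcome, since the SD of the measured changes was 0.29 to 0.40, so it checks the arithmetic and gives no error rate. The correlation expected from a shared wild type was simulated 100 times with normal noise of equal SD in each column, which fixes its value in advance. The overlap was simulated 100 times with noise drawn from the difference of the muscle knockouts within 20 expression bins. Both simulations count real differences between the knockouts as noise. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, centring on medians, quantile normalization, the other litter's wild type and both wild types as control, and, added after the data were seen, a 1.5-fold rule, zeros kept, and a difference of 2-fold from both wild types. The table has 79 entries with joined symbols of overlapping genes and 14 septin genes whose names were turned into dates, and both were kept as listed. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.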

Results

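Gene expression was profiled by RNA sequencing in mice lacking the lamin B receptor, an inner nuclear membrane protein encoded by Lbr, or lamins A and C, the nuclear lamina proteins encoded by Lmna. The 12 samples came from cultured myoblasts, the proliferating precursors of muscle fibres, and from striated muscle, with 6 libraries from each. The deposited table held 22552 genes and 7 columns of FPKM values, a single column per group. Each knockout column and the wild-type muscle column stood for 2 samples, whose separate values were not used here because the table gives a single value for the group. The wild-type myoblasts formed 2 groups of 1 library each, from the Lbr litter and from the Lmna litter. No group value therefore has a replicate error and no litter-matched or muscle difference has a replicate check or a p-value. The only spread between libraries is that of the wild-type myoblasts, on which a single fit, given with the myoblasts, rests. In what follows, a gene rose, fell or changed when it differed by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of genes of low expression.

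The number of genes at 1 FPKM or more was close between groups, from 11315 in wild-type myoblasts of the Lbr litter to 12256 in Lbr-knockout muscle. The 10 most abundant genes took 9.21% to 10.6% of the summed FPKM in the myoblast columns and 20.2% to 26.5% in the muscle columns. Total counts are unknown. Estimated from the spacing of low values, 1 FPKM of a 2 kb transcript corresponded to about 30.8 fragments in the wild-type myoblasts and 8.16 in wild-type muscle. For knockout myoblasts and knockout muscle the figures were 23.5 and 6.35, the last with a weak peak in the Lmna-knockout column. By this estimate low muscle values rest on few fragments. For columns that stand for more than a single sample it depends on how the samples were combined, which is not known.

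The targeted genes were examined first. In Lbr-knockout muscle, Lbr fell from 11.8 to 1.87 FPKM, a log2 change of -2.16. In Lbr-knockout myoblasts Lbr stood at 7.71 FPKM against 16.1 in its own litter's wild type and 14.7 in the other, a log2 difference of -0.97 that did not reach 2-fold. Lmna fell from 147 to 18.5 FPKM in Lmna-knockout myoblasts (log2 change -2.92) and from 59.5 to 22.6 FPKM in Lmna-knockout muscle (-1.36). The labels do not say which part of either gene was deleted, so the remaining signal cannot be assigned to an intact or a truncated transcript. Nor do the pooled values show whether both samples of the Lbr-knockout myoblast column had lost Lbr. Among the other lamina genes, Lmnb2, which encodes lamin B2, fell in Lmna-knockout muscle from 9.13 to 3.59 FPKM (-1.14). Lmnb1, encoding lamin B1, and Emd, encoding emerin, differed by less than 2-fold in every knockout. With own-litter controls in myoblasts, the largest differences were -0.37 for Lmnb1 and -0.55 for Emd, both in Lmna-knockout muscle. Against the other litter's wild type, Emd was at 0.75 in Lmna-knockout myoblasts.

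**Figure D1:**
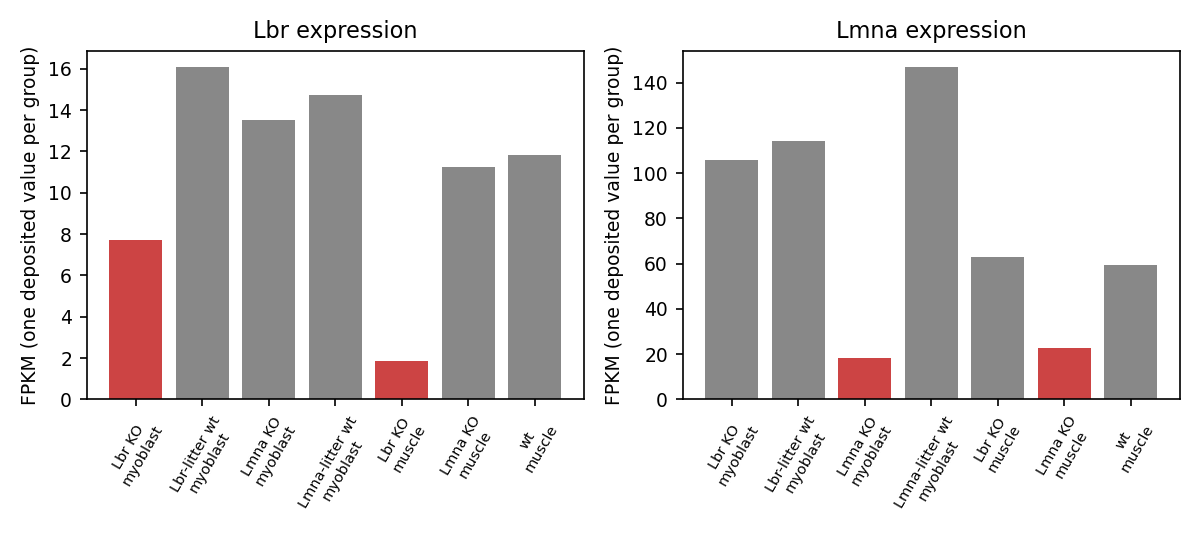
Expression of Lbr (left) and Lmna (right) in FPKM, with a bar for the single deposited value of each of the 7 groups and the knockout columns of the gene in red. Lbr stood at 7.71 FPKM in Lbr-knockout myoblasts and 1.87 FPKM in Lbr-knockout muscle, and Lmna at 18.5 and 22.6 FPKM in the Lmna-knockout columns.

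The comparison of Lbr-knockout myoblasts with wild-type myoblasts of the same litter asked which genes differ in muscle precursors labelled as lacking the lamin B receptor, with the remaining Lbr signal given above. Genes of the contractile apparatus and genes of muscle differentiation were higher in the knockout. Of 37 sarcomere genes, which encode the contractile filaments and their anchors, 26 rose, 0 fell and the median log2 change was 1.26 (interquartile range 0.84 to 1.61). Of 17 regulators and markers of muscle differentiation 11 rose and 0 fell (median 1.13, interquartile range 0.91 to 1.42). All 18 macrophage and leukocyte genes rose in the same comparison (median 1.62, interquartile range 1.48 to 1.84). Schwann cell genes, of which 9 of 11 lay below the wild type, had a median of -0.29 (-0.20 against the other litter's wild type), and 17 interferon genes a median of 0.44 (-0.05 against the other).

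Among the sarcomere genes, Actc1, which encodes cardiac alpha-actin, rose from 36.7 to 147 FPKM (log2 change 1.97), Des, the intermediate filament desmin, from 23.3 to 85.2 FPKM (1.83), and Mylpf, a fast myosin light chain, from 57.5 to 196 FPKM (1.75). Of the 9 genes of developmental contractile isoforms 6 rose (median 1.61), including Myh3, the embryonic myosin heavy chain, from 7.67 to 25.6 FPKM. Of the 9 fast-fibre genes 8 rose (median 1.38), and of the 7 slow-fibre genes 4 rose (median 1.27). The differentiation factor Myog rose from 2.94 to 10.5 FPKM (1.54), and Tmem8c, which encodes the fusion protein myomaker, from 12.8 to 43.0 FPKM (1.67). Of 14 genes of excitation-contraction coupling 6 rose (median 0.64), among them Atp2a1, the calcium pump of fast muscle, with a log2 change of 1.38. The central 95% of medians of random lists matched on expression ran from -0.02 to 0.13 for the sarcomere list and from -0.05 to 0.18 for the regulators. Genes of muscle progenitors had a median of 0.07 and none of the 14 changed.

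Counted over all genes, 298 of 11463 changed in Lbr-knockout myoblasts, 284 higher and 14 lower. With genes listed at 0 kept, 295 were higher and 60 lower. The largest rises included Xist, the RNA that silences an X chromosome (5.84). The labels do not give the sex of the animals, so no Xist difference, here or in the other comparisons, can be assigned to a knockout. Xist was at 0.0057 FPKM in the wild type and 56.6 FPKM in the knockout, and the Y-linked Ddx3y at 21.4 and 11.6 FPKM. The compared columns were therefore not alike in sex-linked expression. Also among the largest rises were Krt18, a keratin of simple epithelia (0.22 to 12.8 FPKM, 3.50), Aldh1a2, an enzyme of retinoic acid synthesis (4.11 to 28.2 FPKM, 2.51), and C1qa, a complement component made by macrophages (1.47 to 11.8 FPKM, 2.38). Ifi202b (3.26), Abhd1 (0.18 to 8.45 FPKM), Yipf2 (2.35) and Cd72 (2.32) completed the 8 largest rises. The largest falls included those of the interferon-inducible Ifi205 (-2.10), the AP-1 transcription factor gene Fosl1 (32.6 to 7.97 FPKM, -1.91), Gtpbp6 (-1.75), Armcx5 (-1.44), the ribosomal protein gene Rpl26 (-1.41), the muscle cytochrome oxidase subunit gene Cox6a2 (-1.39) and Rpap2 (-1.26). Ifi202b, Ifi205 and Rpl26 have close relatives or pseudogenes, and their values are uncertain for that reason. Among imprinted genes there were rises of the growth factor gene Igf2 (72.8 to 171 FPKM, 1.22), the non-coding H19 (54.3 to 155 FPKM) and the cell cycle inhibitor gene Cdkn1c (1.42). Against the other litter's wild type Igf2 was at 1.43 and H19 at 1.62, but Cdkn1c at 0.33. Of the 16 imprinted growth genes 11 lay above both wild types and 0 below both, with the same numbers in Lmna-knockout myoblasts. Both knockout columns stand for 2 samples and each wild type for 1, so this shift cannot be assigned to a knockout.

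Which genes changed depended on the wild-type library: 241 changed against that of the other litter, 74.3% of them higher in place of 95.3%. Of the 284 genes that rose, 52 (18.3%) were also at least 2-fold above the wild type of the other litter, among them 7 of the 26 sarcomere genes, 0 of the 11 regulators and 0 of the 18 macrophage genes, and the wild types differed from each other by 2-fold at 312 genes.

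Lmna-knockout myoblasts were compared with their own litter's wild type to ask the same question of lamins A and C. The muscle genes were lower in this knockout. Of 36 sarcomere genes 24 fell, 0 rose and the median log2 change was -1.51 (interquartile range -2.25 to -0.77). Of the 17 differentiation regulators 11 fell and 0 rose (median -1.12, interquartile range -1.57 to -0.86). None of the 18 macrophage genes changed (median -0.28), though against the other litter's wild type their median was 1.45. Of 11 adipocyte genes 9 lay above both wild types and 1 below both.

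All 8 fast-fibre genes fell (median -2.08), and so did 5 of the 7 slow-fibre genes (median -1.82) and 7 of the 9 developmental isoforms (median -1.61). Myl1, an alkali light chain of fast myosin, fell from 32.0 to 3.43 FPKM (-2.90), Mylpf from 119 to 18.7 FPKM (-2.61), Tnnc2, the fast troponin C gene, from 13.0 to 1.30 FPKM (-2.61), and Tnnt1, the slow troponin T gene, from 21.0 to 2.73 FPKM (-2.56). Mb, which encodes the oxygen carrier myoglobin, fell from 19.2 to 1.29 FPKM (-3.14), and Mybph, a myosin-binding protein gene, had a change of -2.78. Among the regulators and markers, Cav3, encoding the muscle caveolin, changed by -1.72, Tmem8c by -1.66, Actc1 by -1.61 and Smyd1, a methyltransferase of muscle, by -1.59. Of 14 coupling genes 4 fell (median -0.58), but over those with a mean of at least 5 FPKM the median was 0.00348. The random lists for sarcomere genes ran from -0.04 to 0.11.

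In all, 138 of 11462 genes changed, 69 in each direction, and 40 of the 69 that fell belonged to the 7 muscle lists. With genes listed at 0 kept, 79 were higher and 116 lower. Beside Lmna itself and the muscle genes, Rpl26 was among the 8 largest falls (-2.78). The largest rises were Atp6v0c-ps2 (3.74), Abhd1 (2.64), Rbm46 (2.25), Hp, the gene of the plasma protein haptoglobin (2.19), Pisd-ps1 (2.16), the histone gene Hist2h2bb (2.02), the fatty acid carrier gene Fabp4 (4.58 to 20.5 FPKM, 1.94) and the TNF family ligand gene Tnfsf13 (1.84). The pseudogenes Atp6v0c-ps2 and Pisd-ps1 and the histone gene share sequence with other loci, and Hp and Tnfsf13 lay below 5 FPKM in the knockout. All 16 imprinted growth genes were above their wild-type value (median 0.32) without a change of 2-fold in any, whereas 11 were above the other litter's wild type (median 0.17). The 25 mitosis genes had a median of -0.18 with 1 above 0, and of -0.10 with 11 above 0 against the other wild type.

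Against the wild type of the other litter, the sarcomere median was -1.01 and 34 of the 69 falls (49.3%) were again at least 2-fold, 24 of the 34 in the 7 muscle lists. Of the 11 regulators that fell, 2 were again at least 2-fold below, and the list median was -0.50. Myog, at -1.12 against its own wild type, was at 2.89 FPKM in the knockout and 2.94 FPKM in the other wild type, and against that control 518 genes changed, 75.1% of them higher.

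**Figure D2:**
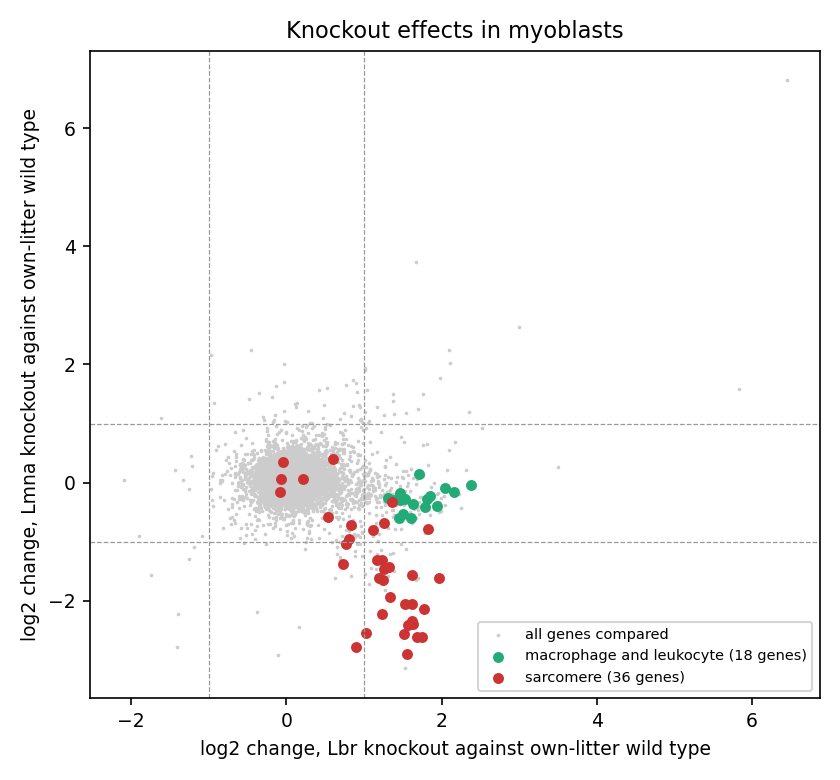
Log2 change of each gene in Lbr-knockout myoblasts (horizontal axis) and in Lmna-knockout myoblasts (vertical axis), each against its own litter's wild type, with 36 sarcomere genes in red, 18 macrophage and leukocyte genes in green and dashed lines at 2-fold. Most sarcomere genes lie at the lower right, with medians of 1.26 and -1.51 in the separate lists, and the macrophage genes lie right of the 2-fold line with a median of -0.28 on the vertical axis.

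The responses of the myoblasts to the knockouts were then set against each other. Muscle genes moved in opposite directions: the difference of the litter-matched changes, Lbr minus Lmna, had a median of 2.77 over 36 sarcomere genes (interquartile range 1.80 to 3.67), with 31 at 2-fold or more. It was 2.53 over the 17 regulators and 2.04 over the 18 macrophage genes. With the wild types exchanged the medians were 1.75, 1.13 and -1.46, so that the macrophage difference turned. The largest single differences were those of Mb (4.67), Myl1 (4.46), Mylpf (4.36), Tnnc2 (4.29) and Xist (4.25), and in the other direction those of Pisd-ps1 (-3.13), Rbm46 (-2.71), Ifi205 (-2.15), Atp6v0c-ps2 (-2.07) and Hist2h2bb (-2.04).

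In total 424 of 11447 genes differed, 370 higher for Lbr and 54 lower, a higher share of 87.3% that was 60.6% with both wild types as control, while 1033 were higher and 1031 lower with the wild types exchanged. Of all 11447 genes, 40 rose in the Lbr knockout and fell in the Lmna knockout, among them Myog, Actc1, Actn2, Myh3 and Tnnt1. Independent lists would give 1.69, but the wild types already differ in muscle genes. Median levels in the Lbr and Lmna litters' wild types were 4.39 and 6.51 FPKM for sarcomere genes and 2.78 and 5.35 FPKM for regulators. Against the other litter's wild type, Myog was at 0.44 and -0.02, Actc1 at 0.90 and -0.54, and Myh3 at 1.23 and -1.95. A further 22 rose in both, against 1.54 for independent lists, including Setdb1, a histone H3 methyltransferase gene (1.06 and 1.05), Fabp4, Abhd1, Yipf2 and the glycolytic Pfkm, and 5 fell in both, Cox6a2, Gtpbp6, Lrfn4, Rpap2 and Rpl26, against 0.08. Both knockout columns stand for 2 samples and both wild types for 1, so shared changes cannot be assigned to the knockouts. Across genes the changes had a Pearson r of -0.02 and a Spearman rho of 0.06, from columns that share no library, and genes are not independent replicates. The litter-matched difference was calculated and not tested, and with the wild types exchanged the count was 2064. A limma fit with both wild types as 1 group set the knockout columns directly against each other, 1 column each and without litter matching. Among its larger log2 differences, Lbr minus Lmna, were 3.81 for Myl1, 3.57 for Myh3, 3.44 for Tnnt1 and -2.35 for S100a7a. The Y-linked Eif2s3y was at 1.82, so sex-linked differences enter as well. Against the wild types, Myh3 was at 1.42 for Lbr and -2.14 for Lmna. The error of this fit comes from the wild types alone and measures no spread among knockout animals, so no count of genes is given.

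**Figure D3:**
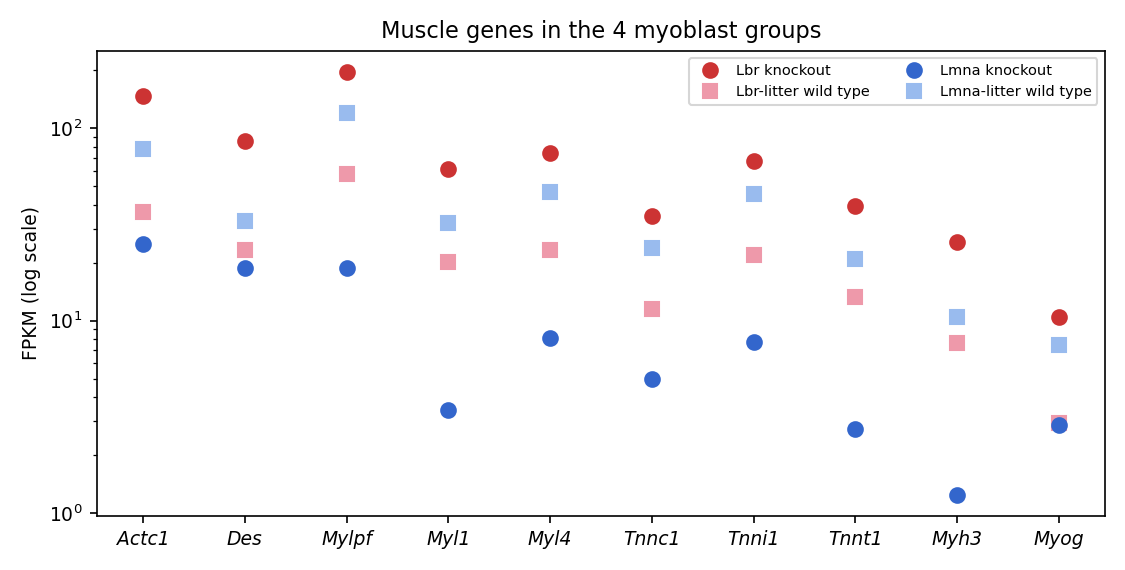
FPKM on a log axis of 10 muscle genes in the 4 myoblast groups, with circles for the knockouts and squares for the wild types, a single deposited value each. For Mylpf the Lbr knockout lies at 196 FPKM, the wild types at 57.5 and 119 FPKM and the Lmna knockout at 18.7 FPKM, whereas for Myog the Lmna knockout and the wild type of the Lbr litter overlap at 2.89 and 2.94 FPKM.

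In striated muscle, the Lbr knockout was compared with the wild-type column that served both knockouts, so the muscle comparisons are not matched by litter. The lists of macrophage, Schwann cell and liver-secreted protein genes had medians above the range of random lists and the cartilage and bone list a median below it, with a minority of members past 2-fold in most, while the sarcomere genes stayed within 2-fold. Of 53 sarcomere genes 0 rose and 0 fell (median -0.12, interquartile range -0.24 to 0.02). Of 13 Schwann cell genes, which mark the myelinating glia of nerves, 3 rose (median 0.62, interquartile range 0.51 to 0.88), and of 16 macrophage genes 4 rose (median 0.58, interquartile range 0.12 to 0.86). Of the 8 cartilage and bone genes 3 fell (median -0.88).

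The myelin gene Mbp rose from 73.4 to 207 FPKM (1.48). The leukocyte phosphatase gene Ptprc rose by 1.33. Of 12 neutrophil genes 3 rose and 1 fell (median 0.36), the calgranulin genes S100a8 and S100a9 at 1.62 and 1.52 and the protease gene Mmp9 at -1.03. Of 7 genes for proteins secreted by liver 4 rose (median 1.12), the albumin gene Alb from 1.54 to 4.53 FPKM. Lymphoid genes, a list chosen after the values were seen, had 16 of 21 members higher (median 1.41), among them the B cell receptor gene Cd79a (2.93 to 18.4 FPKM, 2.30). The atrophy list, genes induced in wasting muscle, had a median of 0.27, with rises only in the metallothionein genes Mt2 (1.19) and Mt1 (1.07). Sln, which encodes the calcium pump inhibitor sarcolipin, rose from 98.9 to 261 FPKM (1.39), Cfd, an adipocyte protease gene, from 67.6 to 220 FPKM (1.69), and the imprinted Nnat from 31.7 to 109 FPKM (1.74).

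A total of 189 of 12080 genes changed, 157 higher and 32 lower. The largest rises were Ccl21a,Gm1987 (4.75), Ccl19 (1.70 to 21.7 FPKM, 3.08), Pisd-ps1 (2.74), Lgals6 (2.53), Cd37 (2.45), Ccl5 (4.76 to 27.6 FPKM, 2.31), Cd79a and H2-Q9 (2.30), of which Ccl19, Ccl5 and Ccl21a are chemokine genes of lymphoid tissue or T cells. The largest falls were the brown fat uncoupling protein gene Ucp1 (67.8 to 3.61 FPKM, -3.90), the bone matrix genes Spp1 (-3.54), Ibsp (-3.41) and Bglap (-2.94), Pisd-ps3 (-3.16), the pancreatic Pnliprp1 (-2.98), Hist1h2ap (-2.93) and the brown fat gene Cidea (15.5 to 1.20 FPKM, -2.90). Ccl21a, Lgals6, H2-Q9, Hist1h2ap and the Pisd pseudogenes have near-identical copies and are uncertain.

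The median over all genes was 0.10 here and 0.13 in Lmna-knockout muscle, and the share of changed genes that were higher, 83.1%, was 72.2% after centring on the medians and 69.8% after quantile normalization. At an estimated 6.35 to 8.16 fragments per FPKM for a 2 kb transcript, genes of a few FPKM carry a wide counting error.

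Lmna-knockout muscle, set against the same wild type, had higher expression of genes of muscle wasting, while its cell division genes lay below the wild type, mostly by less than 2-fold. Of 19 atrophy genes 5 rose, 0 fell and all 19 were above the wild type (median 0.76, interquartile range 0.53 to 1.33). Of 20 p53 targets 3 rose and 5 lay below the wild type (median 0.32, close to the upper end of the random range of -0.05 to 0.30). The 24 mitosis genes were all below the wild type and 2 fell (median -0.62, interquartile range -0.86 to -0.32). Of 53 sarcomere genes 1 rose and 2 fell (median -0.07), within the random range of -0.08 to 0.07.

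Fbxo32, which encodes the ubiquitin ligase atrogin-1, rose from 9.41 to 50.1 FPKM (2.30), Pdk4, a kinase that restrains glucose oxidation, from 171 to 734 FPKM (2.10), and Mt2 and Mt1 from 13.4 to 83.2 FPKM (2.55) and from 38.8 to 227 FPKM (2.52). The cell cycle inhibitor gene Cdkn1a rose from 4.33 to 22.1 FPKM (2.12), the death receptor gene Fas by 1.48 and Sesn1 by 1.15. Racgap1 and Top2a, which act in cytokinesis and in chromosome untangling, fell by 1.11 and 1.08. The 24 S phase genes had a median of -0.38 and the 64 histone genes a median of -0.26. Of the contractile genes, Actc1 fell from 6501 to 1642 FPKM (-1.98) and the slow light chain gene Myl2 from 270 to 127 FPKM (-1.08), while Csrp3, encoding a muscle LIM protein, rose from 80.2 to 255 FPKM (1.65). The 14 fast-fibre genes had a median of -0.35, with a fall in the calcium buffer gene Pvalb (-1.28). Sln rose to 406 FPKM (2.03), Ankrd1, a stress-responsive ankyrin repeat gene, by 1.61 and Fbp2, the muscle fructose bisphosphatase gene, by 1.33.

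Markers of other cells moved in the same column. Of 12 neutrophil genes 6 rose (median 0.99), with Lcn2 at 2.26 and Retnlg at 2.21, and of 16 macrophage genes 2 rose (median 0.37). Of 21 lymphoid genes, the list chosen afterwards, 10 rose (median 0.98). The 19 interferon genes had a median of 0.47 and Cxcl10, an interferon-induced chemokine gene, rose by 1.24. The adipocyte list had a median of -0.02, with 2 members higher and 4 lower, the lipase gene Pnpla2 at 1.46 and the fatty acid desaturase gene Scd1 at -2.51 (63.0 to 10.3 FPKM).

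All told, 325 of 12068 genes changed, 233 higher and 92 lower. Xist (3.61), Ccl21a,Gm1987 (4.18), Atp6v0c-ps2 (2.96), Pisd-ps1 (2.72) and Cd37 (2.46) were among the largest rises, and the largest falls included Ucp1 (67.8 to 1.23 FPKM, -4.95), Cidea (-2.60), Scd1, the pancreatic enzyme genes Amy2a5 (-2.07) and Cpb1 (-2.03), Cited4 (-2.04) and the plasma protein gene Orm1 (-2.02). Pseudogenes and genes with close copies, such as Ccl21a, are uncertain. The share of changed genes that were higher, 71.7%, was 53.9% after centring on the medians and 55.2% after quantile normalization.

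**Figure D4:**
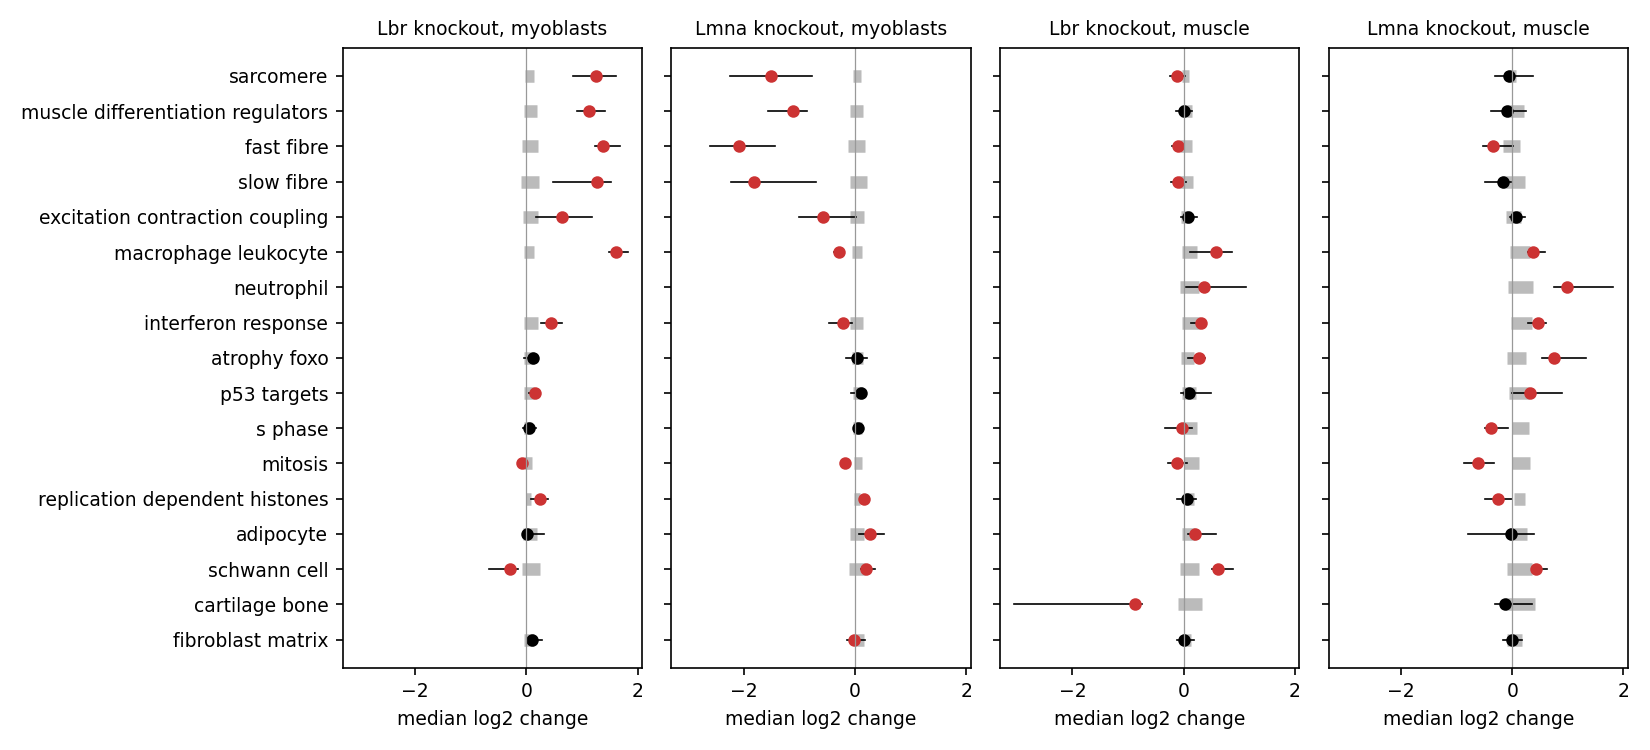
Median log2 change of 17 gene lists (points) in each knockout against its wild type, with black lines for the interquartile range over members, grey bars for the central 95% of medians of 10000 random lists matched on expression, and red points for medians outside it. The sarcomere medians are 1.26 and -1.51 in myoblasts and -0.12 and -0.07 in muscle.

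Both muscle knockouts were next compared directly. Atrophy, neutrophil and bone genes were lower in the Lbr knockout than in the Lmna knockout, with medians of -0.54, -0.63 and -0.76, and mitosis genes were higher, with a median of 0.52 and all 24 members above 0. The bone genes Spp1 (-4.89), Bglap (-4.51) and Ibsp (-2.92) had the largest differences together with Xist (-3.50) and Hist1h2ap (-3.04), and Nnat (2.90), Scd1 (2.59), Rprl2 (2.31), Alb (2.11) and the myelin gene Pmp2 (1.98) lay at the other end. In this comparison 180 of 12069 genes differed, 82 higher in the Lbr knockout and 98 lower.

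Against wild type, 74 genes rose in both muscle knockouts and 6 fell in both, Ucp1, Cidea, Amy2a5, Cela3b, Gm1987 and Pisd-ps3, against 2.91 and 0.20 for independent lists. Gm1987 and Pisd-ps3 fell while the related entries Ccl21a,Gm1987 and Pisd-ps1 rose in both, so the changes of these entries are uncertain. Independent lists are no measure of an unchanged pair that shares a control, for which simulated groups gave a mean of 25.5 genes higher in both (15 to 40) and 24.9 lower in both (13 to 37). The simulation carries no shift of the medians, which raises the number higher in both. The changes had an r of 0.55 and a rho of 0.52 across genes. Unchanged groups simulated against the shared wild type gave an r of 0.50, a value fixed in advance by equal noise in all columns. The covariance was 0.0727 against a simulated 0.0623, a difference of 0.0104. The simulated value was set from the difference between the knockouts, so real differences between them count as noise and no conclusion is drawn. Part of the shared changes may come from the shared wild-type column, which cannot be split.

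Wild-type muscle was set against the mean of the wild-type myoblasts to place the tissues. Genes of mature fibres were far higher in muscle: the parvalbumin gene Pvalb (13.39), the fast myosin heavy chain gene Myh4 (13.01), the creatine kinase gene Ckm (11.79), and the troponin genes Tnnc2 (10.66) and Tnni2 (10.64) led. Of 52 sarcomere genes 47 were at least 2-fold higher (median 6.48), and the 34 genes of oxidative phosphorylation had a median of 2.58. All 25 mitosis genes were lower (median -3.34), as were 20 of 23 genes of cholesterol synthesis (median -2.46). The myoblasts were higher in Inhba (-8.68), Actg2 (-8.53), Thbs1 (-8.43) and Ptgs2 (-7.32), genes of an activin subunit, smooth muscle actin, thrombospondin and prostaglandin synthesis. Of 12145 genes 6532 differed, 32.2% of them higher in muscle, a share of 53.4% after centring and 45.0% after quantile normalization. Library kit and tissue changed together and cannot be told apart.

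The effect of each knockout was finally compared between tissues, matched by litter in myoblasts but not in muscle. For Lbr, the sarcomere change was smaller in muscle than in myoblasts by a median of -1.29 over 51 genes, and for macrophage genes by -1.20 over 19 genes, while Schwann cell genes had a median difference of 0.99. Against the other litter's wild type these were -0.73, 0.58 and 1.04, so that the macrophage difference turned. For Lmna, the sarcomere change was higher in muscle by a median of 1.14 over 50 genes, and atrophy genes by 0.85 over 19. The 1.14 depends on the control, as the sarcomere median in Lmna-knockout myoblasts was -1.51 against their own wild type and -1.01 against the other. The largest differences for Lmna included those of Csrp3, which led, Thbs4 (3.15), Sln (2.89), Cd37 (2.86) and Myh3 (2.70), and of Abhd1 (-3.66), Scd1 (-2.84), Hist2h2bb (-2.64) and Mdk (-2.55). For Lbr they were Ccl21a,Gm1987 (4.75), Pisd-ps1 (3.71), Ccl19 (3.03), Akr1b3 (2.68) and Cd79a (2.27), and Xist (-5.73), Pisd-ps3 (-4.95), Spp1 (-4.05), Krt18 (-3.87) and Ibsp (-3.41). The Lbr effect differed at 348 of 12113 genes, 103 of them (29.6%) higher in muscle, a share of 55.4% against the other litter's wild type and 43.2% against both. The Lmna effect differed at 456 of 12076, 301 of them higher. For Lmna the higher share of 66.0% was 51.6% after centring and 48.1% after quantile normalization, and with the other litter's wild type as control it was 47.7% of 1092.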

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

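Every test in this part was chosen after the result it bears on was seen. Muscle gene lists had medians of opposite sign in Lbr- and Lmna-knockout myoblasts, each at least 0.5 in size and outside the range of random lists. The medians were 1.26 and -1.51 for sarcomere genes, 1.13 and -1.12 for differentiation regulators, 1.61 and -1.61 for developmental isoforms, 1.38 and -2.08 for fast-fibre genes, 1.27 and -1.82 for slow-fibre genes, and 0.64 and -0.58 for excitation-contraction coupling, the last of which was 0.00348 over genes with a mean of at least 5 FPKM. The litter-matched difference between the knockouts was not tested, as each litter has 1 column per genotype, and no group had enough values to look for outlying samples.

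A wild-type library with unusual muscle gene levels was examined by the medians of Lbr and Lmna against the other litter's wild type. These were 0.69 and -1.01 for sarcomere, 0.66 and -1.001 for developmental, 0.83 and -1.54 for fast-fibre and 0.53 and -1.15 for slow-fibre genes. The wild types' own differences were -0.55, -0.59, -0.60 and -0.46. The Lmna medians exceed these in size and argue against this explanation as the whole cause for Lmna. Those for Lbr are close to them in size, and with a single library per wild type they cannot decide it. The lists share members and are not separate evidence. For the regulators (0.50 and -0.50, with -0.76 between the wild types) and coupling genes (0.47 and -0.44) the explanation by a wild-type library stays open. For Lbr 16 of 17 and 11 of 14 members lay above both wild types, and for Lmna 12 of 17 and 8 of 14 below both. Members of a list are not replicates and each group is a single column, so these counts do not decide it. A shift common to columns built from 2 libraries would give both knockouts the same sign against a given wild type. Against the Lbr litter's wild type the sarcomere medians were 1.26 for Lbr and -1.01 for Lmna. Against that of the Lmna litter they were 0.69 and -1.51, so a common shift alone would not give the pattern. The median difference of 2.77 between the litter-matched effects also holds the difference between the wild types. Other effects of how the columns were built were not tested. A different share of cells in differentiation may account for the pattern: Myog moved with the list by at least 1.12 in each knockout against its own litter, but by 0.44 and -0.02 against the other wild type, so this cannot be told apart from a difference between cultures or litters. A different share of muscle cells and fibroblasts in the cultures was not tested and stays open. Fibroblast matrix genes had median levels of 174 and 168 FPKM in the Lbr knockout and its wild type. In the Lmna knockout and its wild type they had 204 and 199 FPKM. Their median log2 changes against the own litter were 0.097 for Lbr and -0.011 for Lmna, and those of muscle progenitor genes 0.067 and 0.0017. An effect of the knockouts themselves stays open, since genotype and culture vary together.

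The 18 macrophage genes, all higher in Lbr-knockout myoblasts, had a median level of 34.1 FPKM there, 10.4 FPKM in the same litter's wild type, and 29.1 and 38.3 FPKM in the Lmna knockout and its wild type. Low macrophage RNA in the Lbr litter's wild-type library is a candidate explanation, since against the other wild type the median was 0.0015. An effect of the Lbr knockout on macrophage genes within the litter cannot be told apart from it: the knockout lay above both wild types for 9 of 18 members, and each wild type is a single library. Among the abundant members, C1qb stood at 99.3, 23.3, 86.5 and 92.2 FPKM in the same order of columns. The labels name no sort that would remove macrophages.

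Of the genes at 10 FPKM or more in both wild-type myoblast libraries, 12 were listed at 0 in both myoblast knockouts, including Gnas, the G protein alpha subunit gene (899 and 871 FPKM in the wild types), and Tpm1, the tropomyosin gene (1960 and 2905 FPKM). Failed estimates in columns built from 2 libraries may explain this, as 0 genes showed the reverse, but all 12 genes were above 0 in both muscle knockouts, whose columns are also built from 2 libraries. The explanation therefore stays open. No biological explanation was tested, and these genes entered no comparison in which they are listed at 0.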

How the results depend on the processing

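The limma fit, the 1.5-fold rule, the zeros kept and the count beyond both wild types were chosen after the data were seen, the other settings before. No paired analysis was possible because the columns carry no replicate number. Omission of single libraries, fits of other library sets and other variance priors were not run, as there is 1 column per group. A gene set test (camera) was also run on the limma fit with both wild types as 1 group. It is not used, because each knockout is 1 column in it. Lists such as macrophage and histone genes also moved as a whole between the wild types (-1.75 and -0.91).

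Counts are given in the order Lbr and Lmna in myoblasts, their difference, Lbr and Lmna in muscle, their difference, and the Lbr and Lmna effects between tissues, against 298, 138, 424, 189, 325, 180, 348 and 456. They were 486, 223, 638, 457, 725, 404, 872 and 1072 with a pseudocount of 0.1, and 86, 32, 151, 48, 98, 56, 101 and 128 with a pseudocount of 5, where the tissue count was 4115. With a mean of at least 5 FPKM they were 132, 60, 180, 67, 187, 109, 196 and 268, as fewer genes enter. With the 1.5-fold rule they were 695, 391, 943, 832, 1516, 914, 1324 and 1918. With the other litter's wild type the Lmna count was 518, the difference 2064 and the Lmna effect between tissues 1092. With both wild types as control the Lbr count was 152, and beyond both wild types at once 61 genes changed for Lbr and 74 for Lmna. All other counts were within 1.5 times. With zeros kept, however, the genes lower in myoblasts went from 14 to 60 for Lbr and from 69 to 116 for Lmna.

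The correlation in myoblasts, -0.02, was 0.0576 as rho, 0.0661 with a mean of at least 5 FPKM, -0.0842 with both wild types as control and 0.35 with zeros kept. It was -0.55 with the wild types exchanged, where each enters the wrong comparison. In muscle, 0.55 became 0.52 as rho, 0.59 and 0.52 with pseudocounts of 0.1 and 5, and 0.53 with a mean of at least 5 FPKM.

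Of the list medians over all settings, 621 moved by less than the SD of random lists, 400 by more, and 22 reversed. Only medians outside the range of random lists in the main setting could count as reversed. Changes of sign in the other lists are included in the 621 and 400. With the other wild type as control, reversals in Lbr-knockout myoblasts were oxidative phosphorylation (-0.24), p53 targets (-0.13), endoplasmic reticulum stress (-0.31), interferon (-0.0529), neuronal (0.11), histone (-0.69) and ribosomal protein genes (-0.28). In Lmna-knockout myoblasts they were muscle energy metabolism (0.0408), endoplasmic reticulum stress (0.43), interferon (0.13), fibroblast (0.0266) and macrophage genes (1.45). With both wild types, they were oxidative phosphorylation (-0.0367), endoplasmic reticulum stress (-0.0766), histone (-0.20) and ribosomal protein genes (-0.0508) for Lbr, and endoplasmic reticulum stress (0.30) and macrophage genes (0.58) for Lmna. With a mean of at least 5 FPKM, coupling genes (0.00348) and energy metabolism (0.12) in Lmna-knockout myoblasts and S phase genes in Lbr muscle (0.0254) reversed, and with no filter the immediate early genes in Lbr muscle (0.0372). The cause was not tested. The sarcomere and regulator medians in myoblasts reversed under none of these settings. By the estimate from low values depth limits muscle most, where a 2 kb transcript at 1 FPKM rests on about 6.35 to 8.16 fragments.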

Other observations

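The values in this part were picked out after they were seen, and no explanation of them was tested. Wild-type myoblasts of the Lbr litter differed from those of the Lmna litter in whole gene groups: the 62 replication-dependent histone genes had a median log2 difference of -0.91 with 19 at 2-fold or more, the 18 macrophage genes -1.75 with 16, and the 17 differentiation regulators -0.76 with 4. The SD of the log2 difference over all genes was 0.43 between the wild types, against 0.33 for Lbr-knockout and 0.29 for Lmna-knockout myoblasts against their own wild types. Smooth contractile and SRF target genes had a median of 0.22 in Lmna-knockout myoblasts with all 20 members above their own wild type and none at 2-fold.

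Xist, which marks cells with a silenced X chromosome, stood at 56.6 FPKM in Lbr-knockout myoblasts, 0.0057 in their wild type, 22.1 in Lmna-knockout myoblasts and 6.67 in theirs, and at 0.099, 11.4 and 0.015 in Lbr-knockout, Lmna-knockout and wild-type muscle. The Y-linked Ddx3y was above 0 in all 7 columns, at 11.6, 21.4, 8.90, 8.0, 16.6, 27.5 and 19.5 FPKM in the same order, and so was Eif2s3y, from 5.83 to 52.5 FPKM. The single wild-type library of the Lmna litter thus held Xist and Y-linked RNA together, as did both myoblast knockout columns and the Lmna-knockout muscle column. The sex of the animals is not in the labels.

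In muscle, pancreatic enzyme genes were lower than in wild type in both knockouts, with medians of -1.45 over 5 genes and -1.47 over 6, and the brown fat list had medians of 0.02 and 0.49 over 6 genes with 2 falls in each. Spp1 and Bglap fell in the Lbr knockout and rose in the Lmna knockout, by 1.35 and 1.57, and Nnat did the opposite, with -1.16 in the Lmna knockout. Actc1, Gm7325, Lmna and Rpl26 were the 4 genes that fell in both tissues in the Lmna knockout, against 0.29 for independent lists, and 2 of them, Lmna and Rpl26, were also 2-fold below the other litter's wild-type myoblasts. In the Lbr knockout 25 genes rose in both tissues, against 1.35, among them the leukocyte genes Ptprc, Laptm5, Coro1a and Cd53, but only 2, Sln and the pseudogene Atp6v0c-ps2, were also 2-fold above the other litter's wild-type myoblasts.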
